A study of Huso dauricus x Acipenser schrenckii with 16 samples.

How the data were processed

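RNA from the ovary of adult hybrid sturgeon females was measured in 16 libraries, 8 labelled high yield and 8 low yield. Per the labels, poly(A) RNA was captured and fragmented, the second strand was digested, and adapters were trimmed with cutadapt 1.9. The aligner, the counting program, the genome build and the annotation release are not given in the sources used here. The table names sequences only by database identifiers of an unstated build, so gene positions are not printed. The deposited table gives, per the file headers, counts and FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for 41685 genes in each library. The values of the deposited counts stand in a fixed ratio to the FPKM of the same gene in each library, so the counts may have been computed from read coverage and sampling noise around them need not be Poisson. Totals ran from 37362125 to 60873931 counts per library.

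Genes were tested on the counts with edgeR 4.0.16, the test chosen before the data were examined for a table that holds counts. Low counts were removed with filterByExpr, libraries were scaled with TMM, and a quasi-likelihood F test compared 8 high-yield with 8 low-yield libraries, two-sided, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Its p-values rest on the spread between libraries, counting error included. In high yield part of that spread lies within the near-identical pairs described below. The SE of a log2 fold change is the one implied by the F statistic. All log2 fold changes are high yield over low yield. CPM values are TMM-scaled.

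The near identity of high-yield libraries 1 and 5, 2 and 6, 3 and 7, and 4 and 8 was found in the data, from Spearman's rho of log2 CPM, the variance of counts around a common level in units of Poisson variance (genes with at least 20 counts), and genes with at least 30 counts in 1 library and 0 in the other. For this reason means and SDs in high yield are over 4 pair means, and each test was repeated on the summed counts of each pair, 4 against 8. The planned test treats the 8 as independent, which makes its p-values too small if the members of a pair are not.

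Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and lists of at least 5 tested genes, adjusted over 32 lists, and again with an estimated correlation and with fry. The symbols in the lists were fixed before the data were examined. Of the rows, 37878 carried only a locus number, and no reference table was at hand to look up their symbols, so members were matched by symbol and also by the protein description in the table. This wider matching was chosen after the table was seen. List scores are mean z-scores of log2 CPM over members, compared by a two-sided exact permutation test over 12870 splits (8 against 8) or 495 splits (4 against 8). Pathways given in the table with at least 10 tested genes were tested with camera in the same way.

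The genes named in the text follow a rule fixed before the data were examined. They are the 12 genes with the largest absolute log2 fold change in each direction that passed and had a name, filled up by smallest p to 10 where fewer passed, up to 4 members with the smallest p of each called list, and 28 genes of ovary, yolk and fat biology whether or not they passed. Where several rows matched any of these 28, the one with the highest mean count was taken.

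Alternatives were DESeq2 1.42.0, limma on log2(FPKM + 1) with a mean FPKM of at least 1, other pseudocounts, filters and scalings, a covariate built from 7 marker lists, an exact rank-sum test, and leaving out each library. Pair-summed counts, pair means of the principal components, 1 library per pair, voom with the pair as a random effect, omission of low-yield 2 and 5 or 2 and 6, library size alone as the scaling, and symbols alone were added after the data were seen. In each test of other splits, 100 were drawn with a fixed seed, and 10000 random lists matched on expression and on a length derived from the ratio of counts to FPKM were drawn for the length test. Outlying samples were found by Dixon's ratio, with critical values of 0.526 for 8 and 0.829 for 4 values.

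The pipeline was tested on simulated data with 200 changed genes. All simulated libraries were drawn independently of each other, without near-identical pairs. The false calls given for 8 against 8 therefore do not show how that test behaves on the real high-yield pairs. With 8 against 8, edgeR recovered 26% of the 2-fold and 56% of the 4-fold changes with 5 false calls, and DESeq2 43% and 73% with 35 false calls. With 4 against 8, edgeR recovered 4% and 44% with 3 false calls, and DESeq2 18% and 61% with 69 false calls. Camera called the shifted list and 0 of 30 unshifted lists, whose genes were drawn independently of each other. R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.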

Results

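The series profiled ovary RNA from adult females of a farmed hybrid sturgeon, a cross of a Huso dauricus mother and an Acipenser schrenckii father. One population kept at the farm was ranked as giving a high yield of caviar, the ripe egg mass of the ovary, and another as giving a low yield. The labels give 8 females in each group, 1 poly(A)-selected library per female, so the comparison asks which ovarian transcripts differ between the yield groups. Each yield group is a different population, so yield cannot be told apart from other differences between the populations. The deposited table held counts for 41685 genes in 16 libraries, with totals from 37362125 to 60873931 counts per library. Between 29417 and 36856 genes had at least 1 count in a library. The 10 genes with the most counts took from 3.14% to 8.24% of a library.

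The 8 high-yield libraries formed 4 near-identical pairs, high-yield 1 with 5, 2 with 6, 3 with 7 and 4 with 8. Spearman's rho between the log2 CPM values of a pair lay between 0.989 and 0.995 across genes, while all other pairs of libraries reached 0.970 at most, between low-yield 3 and low-yield 4. Counts within a pair varied around a common level with a median dispersion of 4.19 to 5.54 times Poisson sampling, against 20.1 or more in every other pair of libraries. No low-yield library had such a partner. Each high-yield pair was therefore counted as 1 sample in the means and SDs below (n = 4) and each low-yield library as 1 (n = 8). The gene and list tests over 16 libraries were repeated with the counts of each pair summed, 4 samples against 8. Unless another setting is named, the p-values and SEs of genes and lists below are over 16 libraries and treat the pairs as independent.

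**Figure D1:**
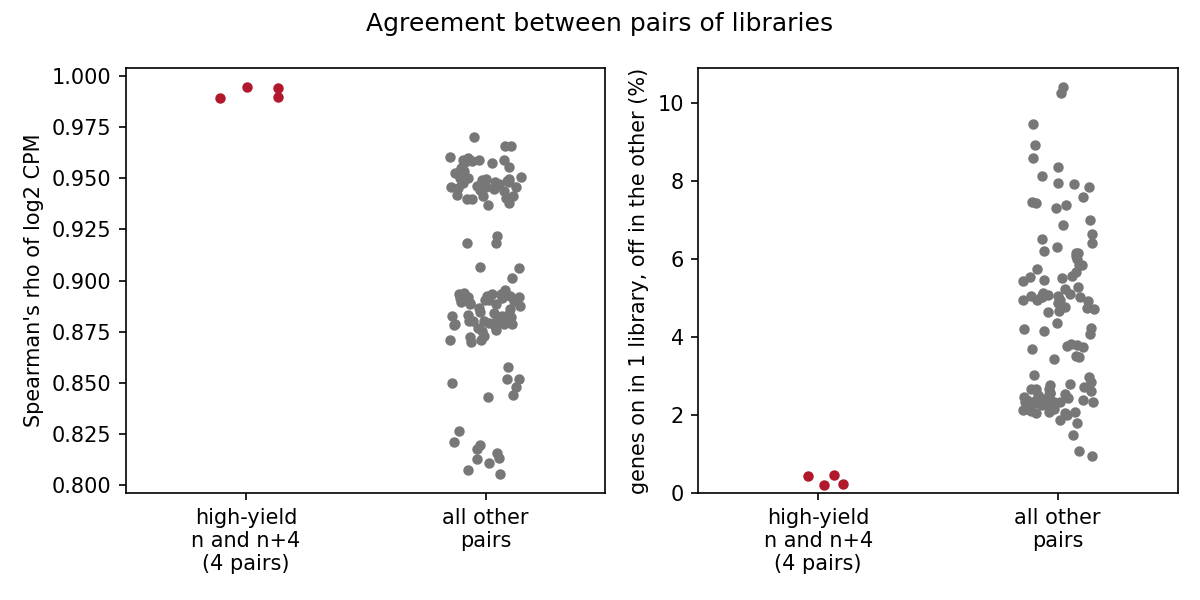
Agreement between pairs of libraries, 1 point per pair: Spearman's rho of log2 CPM across genes (left) and the percentage of genes with at least 30 counts in 1 library that had 0 in the other (right). The 4 high-yield pairs lie above 0.989 and at or below 0.462%, outside the range of all other pairs.

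The first principal component of log2 CPM held 33.3% of the variance and set high-yield 1, 2, 5 and 6 and low-yield 5 (scores from -146 to -126) apart from high-yield 3, 4, 7 and 8 (65.58 to 76.20) and the other low-yield libraries (52.84 to 89.92), with low-yield 2 between them at -42.92. The second component, 15.5% of the variance, set low-yield 2 (-167) and low-yield 5 (-154) apart from all others (-4.74 to 76.2). In a two-sided exact permutation test over 16 libraries, adjusted over 4 components, group means differed on the fourth (7.17% of the variance, p = 0.0106, adjusted p = 0.0423), and the adjusted p was 0.0513 on the second (unadjusted p = 0.0256) and 0.243 on each of the others. Over pair means, 4 against 8, exact adjusted p was 0.0808 on the fourth component, 0.263 on the second and 0.358 on each of the others. Low-yield 2 and 5 also carried the highest scores of the fibroblast and matrix, endothelium, leukocyte, smooth muscle and granulosa cell marker lists. For the fibroblast and matrix list these scores, mean z-scores over the members, were 1.46 and 1.69, against -0.40 to -0.003 in the other low-yield libraries.

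**Figure D2:**
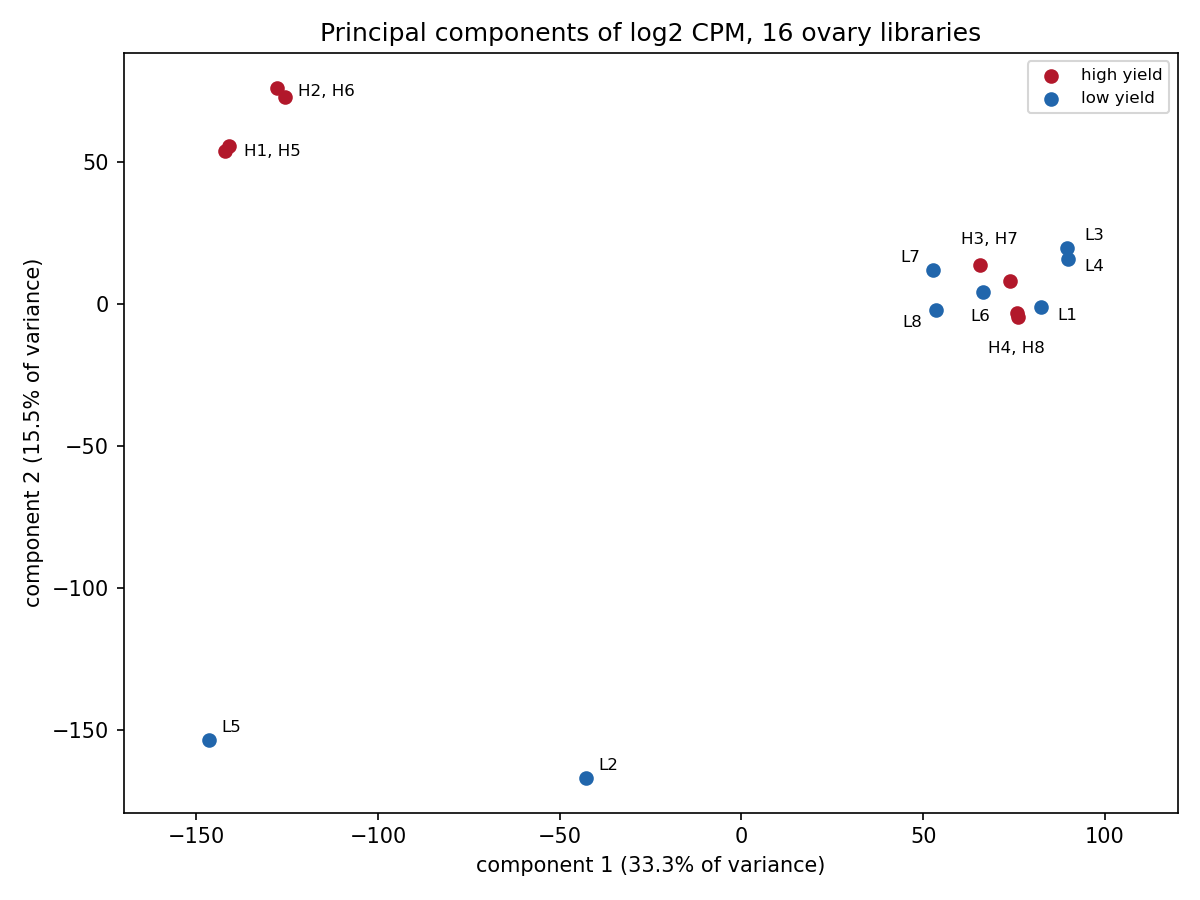
First and second principal components of log2 CPM over the tested genes, with the share of variance on each axis and 1 point per library (H, high yield, red; L, low yield, blue). The high-yield pairs fall together, high-yield 1, 2, 5 and 6 lie at the left, and low-yield 2 (-167) and 5 (-154) lie lowest on the second component.

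The gene cep15, which encodes a centrosomal protein, stood at 18.2 ± 7.01 CPM (SD, n = 4) in high-yield and 4.70 ± 2.34 CPM (SD, n = 8) in low-yield ovaries, a log2 fold change of 1.95 (SE 0.30, edgeR adjusted p = 0.0249). The other higher gene, cog2, a subunit of a Golgi tethering complex, stood at 57.8 ± 9.48 against 31.6 ± 6.68 CPM (log2 fold change 0.87, SE 0.145, adjusted p = 0.0410). In both genes each of the 4 high-yield pair means lay above every low-yield library. Both genes were picked by p from these same values, so this adds no separate support. They were the 2 higher genes among the 16 of 27653 that passed an adjusted p under 0.05 over 16 libraries, and 14 were lower. The wider set did not share this balance. At an unadjusted p under 0.05, 2531 genes were higher and 2953 lower over 16 libraries, and 1553 higher and 1004 lower with pairs summed. With the high-yield pairs summed, edgeR called 0 of 30009 genes, 2557 genes had an unadjusted p under 0.05, the smallest adjusted p was 0.574, and DESeq2 called 86, all 16 genes among them. The log2 fold changes with pairs summed were 1.99 for cep15 and 0.90 for cog2, and -2.63 for LOC117399558 and -1.89 for bag3, which are among the 14 lower genes.

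Among the 14 genes lower in high-yield ovaries the largest fold change was that of LOC117399558, a platelet-type 6-phosphofructokinase, an enzyme of the committed step of glycolysis. It stood at 1.9 ± 0.509 CPM in high-yield and 12.1 ± 7.38 CPM in low-yield ovaries. Its log2 fold change was -2.67 (SE 0.38, adjusted p = 0.0249 over 16 libraries, SE 0.54 and adjusted p = 0.574 with pairs summed). The co-chaperone gene bag3 stood at 2.03 ± 0.670 against 7.76 ± 2.73 CPM (log2 fold change -1.93, SE 0.29, adjusted p = 0.0249). Also lower were gamma-sarcoglycan (LOC117406076) by a log2 fold change of -2.19, the actin cross-linker filamin-B (LOC117964055) by -1.53 and non-erythrocytic spectrin alpha (LOC131696782) by -1.23. Further genes among them were ZMYND11 (LOC117400200, log2 fold change -1.84), the maintenance DNA methyltransferase 1 (LOC117966883, -1.50, from 44.4 ± 18.1 CPM in low-yield to 15.7 ± 3.90 CPM in high-yield ovaries) and the histone demethylase KDM2B (LOC117426610, -1.14). The PH and SEC7 domain protein 1 gene (LOC117970723, -2.47), both rows of nck-associated protein 5 (LOC117401092, -1.28, and LOC131709222, -1.24) and SEC14-like protein 1 (LOC117424579, -1.04) completed the 12 largest, and a second spectrin alpha gene (LOC117396909, 74.7 ± 4.86 against 149 ± 43.5 CPM) and ZNF423 (LOC117425917, -0.91) were the others. For 8 of the 12 largest, namely the phosphofructokinase, LOC117970723, gamma-sarcoglycan, bag3, ZMYND11, filamin-B, KDM2B and SEC14-like protein 1, each of the 4 pair means lay below every low-yield library. The 12 were picked from these same values, so this adds no separate support.

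The next 8 genes by p in the higher direction fell short of the threshold, with adjusted p from 0.0504 to 0.0563. They were FKBP11, a prolyl isomerase of the endoplasmic reticulum (LOC131720900, log2 fold change 1.14), SGT1 (LOC117406587, 0.81), the sialyltransferase ST6GAL2 (LOC117405923, 0.78), the ubiquitin ligase TRAIP (LOC117413871, 0.59), integrin beta-1-binding protein 1 (LOC117402524, 1.52), ATF7IP2 (LOC117418235, 0.58), zgc:110366 (1.49) and CCDC124 (LOC117966260, 0.83). The edgeR count over 16 libraries was not stable. Leaving out 1 library gave 0 genes for each of high-yield 1, 2, 3, 5, 6 and 8 and low-yield 1, 2, 4 and 6, where 4416 to 5671 had an unadjusted p under 0.05. It gave 4 without high-yield 4, 2 without high-yield 7, 1 without low-yield 3, 32 without low-yield 5, 29 without low-yield 7 and 536 without low-yield 8. The count was 3 without both low-yield 2 and 5, 26 (7 higher, 19 lower) with median-of-ratios scaling in place of TMM, and 1624 with DESeq2. Sturgeons carry duplicated genes, so counts of near-identical copies, such as the nck-associated protein 5 rows, may be shared and are uncertain.

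**Figure D3:**
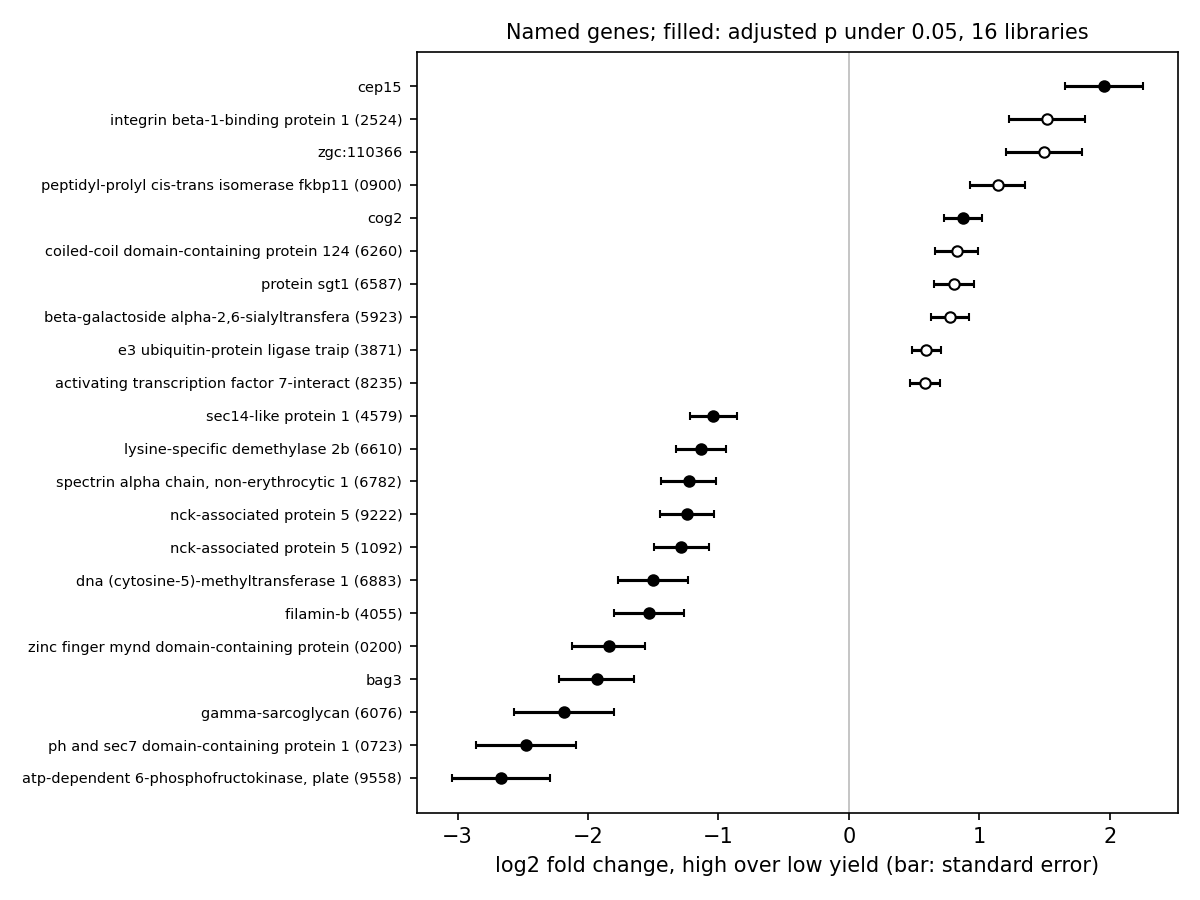
Log2 fold change of high-yield over low-yield ovaries for the genes named by rule in the gene test over 16 libraries (bars, standard error; filled points, adjusted p under 0.05; open points, above it). The 12 lower genes lie between -2.67 and -1.04 and the 10 higher ones between 0.58 and 1.95.

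Of 32 gene lists whose symbols were fixed before the data were examined, 8 shifted as a group over 16 libraries in camera with its preset correlation, 2 higher and 6 lower in high-yield ovaries. With an estimated correlation 0 of the 32 did, over 16 libraries or with pairs summed, and fry called 0. Most rows carry no symbol, so members were also matched by protein description, a rule added after the table was seen, and by symbol alone 12 lists could be tested and 1, oxidative phosphorylation, was called. Leaving out 1 library gave 3 called lists without low-yield 5, 4 without low-yield 2, 5 without low-yield 8, 6 without high-yield 4 and 7 to 9 otherwise. Members of the oxidative phosphorylation list, nuclear genes of the respiratory chain and ATP synthase, lay higher: all but 17 of 142 had a positive fold change, with a median log2 fold change of 0.37 (adjusted p = 1.49e-10, 4.58e-09 with pairs summed, 0.787 with an estimated correlation). None of the members passed the gene test, over all genes or adjusted over the list alone (0 of 142 in both). The complex I subunit NDUFS4 (LOC117403663) stood at 32.9 ± 11.5 CPM in high-yield against 15.1 ± 7.36 CPM in low-yield ovaries, and NDUFB4 (LOC117406729) at 30.1 ± 2.70 against 18.3 ± 7.29 CPM. NDUFB5 (LOC117417075) and NDUFA8 (LOC117396796) had log2 fold changes of 0.62 and 0.55.

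Cytosolic ribosomal protein genes lay higher too, with 124 of 150 members positive and a median log2 fold change of 0.23 (adjusted p = 6.21e-05, 8.96e-05 with pairs summed, 0.817 with an estimated correlation). No member passed over all genes or adjusted over the list alone (0 of 150). RPL19 (LOC117433334) stood at 414 ± 81.8 against 287 ± 93.0 CPM, RPL10A (LOC117428699) at 390 ± 228 against 230.0 ± 86.7 CPM, and RPL13A (LOC117414189) and RPL12 (LOC117396858) had log2 fold changes of 0.57 and 0.71. High-yield 3 and 7 held the highest ribosomal protein score (pair mean 1.30), and the other 3 pair means lay between -0.26 and -0.01. Without low-yield 2 and 6 the ribosomal protein list was not called (median 0.059, adjusted p = 0.591), and the oxidative phosphorylation list was, at a median of 0.18 in place of 0.37 (adjusted p = 0.00271). Without low-yield 2 alone the oxidative phosphorylation median was 0.25. The ribosomal protein median was 0.15 without high-yield 3, 0.14 without high-yield 7 and 0.35 without low-yield 8, and the list stayed called each time. Omission of high-yield 3 or 7 left its near-identical partner in the fit. These fits therefore do not show whether the call rests on that pair, and omission of the whole pair was not tested.

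Marker lists of the ovarian stroma and its vessels lay lower in high-yield ovaries. In the fibroblast and matrix list 43 of 46 members had a negative fold change, with a median of -1.56 (adjusted p = 0.000584, 0.000668 with pairs summed, 0.787 with an estimated correlation). Over all genes 0 members passed, and 15 passed adjusted over the list alone. Collagen XII alpha-1 (LOC117402299) stood at 2.09 ± 0.980 CPM in high-yield and 22.3 ± 36.9 CPM in low-yield ovaries, with 91.4 and 71.6 CPM in low-yield 2 and 5 and 1.44 to 3.47 CPM in the other low-yield libraries. The second collagen XII row (LOC117410940), col6a3 and collagen I alpha-1 (LOC117433526) had log2 fold changes of -1.88, -2.56 and -1.77, and the value of col6a3 was -1.33 without low-yield 5 and 0.02 without both low-yield 2 and 5.

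The endothelium list, with 28 of 30 members negative, had a median log2 fold change of -1.64 (adjusted p = 0.0118, 0.00349 with pairs summed). Its leading members were the VEGF receptor genes VEGFR2 (LOC117420387, -3.40) and VEGFR1 (LOC117407053, -2.10, and LOC131728756, -2.17) and cadherin-5 (LOC117424661, -2.71). The receptor genes were low in abundance. VEGFR2 stood at 0.405 CPM in high-yield against 4.28 CPM in low-yield ovaries, and the VEGFR1 rows at 0.202 against 0.870 and 0.119 against 0.539 CPM. The cadherin-5 value rests on low-yield 5 (18.7 CPM) and 2 (4.00 CPM), with -0.90 without low-yield 5 and 0.45 without both, and all 4 high-yield pair means lay above the low-yield median. In the smooth muscle list 32 of 37 members were negative (median -1.52, adjusted p = 0.0312, 0.0238 with pairs summed). Myosin-11 (LOC117417975), the smooth muscle heavy chain, stood at 1.91 ± 0.410 against 14.9 ± 29.8 CPM, smooth muscle myosin light chain kinase (LOC117408899) had a log2 fold change of -2.53, and without low-yield 5 the values were -1.35 for myosin-11 and -0.41 for the kinase, and without both low-yield 2 and 5 they were 0.33 and 0.46. Both rows of the pericyte proteoglycan CSPG4 had -1.52 (LOC117403816) and -1.30 (LOC117403523). In the leukocyte list 24 of 31 members were negative (median -1.19, adjusted p = 0.0245, 0.0740 with pairs summed), led by the complement C1q subunits made by macrophages: C1QC (LOC117397236, -3.07, and LOC131708114, -2.50), C1QB (LOC131708104, -3.04) and C1QA (LOC131708117, -2.65). In the granulosa cell list, markers of the somatic cells that surround the oocyte, 16 of 18 members were negative (median -1.09, adjusted p = 0.0433, 0.00799 with pairs summed), with LHX9 (LOC131707143) at 0.233 ± 0.268 against 2.47 ± 2.44 CPM, the Wilms tumor gene (LOC117434596) at -2.97 and both anti-Mullerian hormone rows at -0.86 (LOC117428873) and -0.96 (LOC117401371). Adjusted p with an estimated correlation was 0.787 for each of these 4 lists. Members that passed adjusted over the list alone numbered 3 in the endothelium, 0 in the smooth muscle, 4 in the leukocyte and 1 in the granulosa cell list, and 0 of each list passed over all genes. Without both low-yield 2 and 5 the log2 fold change was -3.25 for VEGFR2 and -3.63 for LHX9, but -0.88 for the Wilms tumor gene and from -1.12 to -0.25 for the 4 C1q rows.

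The calls of these lists rested on few libraries. Without low-yield 5 alone all 5 calls ended, with medians of -0.78 for fibroblast and matrix (adjusted p = 0.140), -0.62 for endothelium (0.494), -0.71 for leukocyte (0.196), -0.30 for smooth muscle (0.857) and -0.97 for granulosa cell (0.140). Without low-yield 2 alone the calls of endothelium (median -1.45, adjusted p = 0.0978), leukocyte (-0.62, 0.199), smooth muscle (-1.51, 0.0978) and granulosa cell (-0.60, 0.147) ended, and that of fibroblast and matrix stayed (-1.38, 0.0322). Leukocyte, smooth muscle and granulosa cell also lost theirs without low-yield 8 (adjusted p = 0.0557 for each), smooth muscle without high-yield 4 (0.0523), and granulosa cell without low-yield 7 (0.0722) and with library size only as the scaling. Leukocyte lost its call without low-yield 2 and 6 (adjusted p = 0.116), and fibroblast and matrix and smooth muscle lost theirs with a mean FPKM of at least 5. Without both low-yield 2 and 5 none of the 5 lists was called, with adjusted p from 0.530 to 0.938 and medians from -0.33 to 0.15.

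The egg envelope list, the zona pellucida glycoproteins and related genes, had 185 of 242 members negative, with a median log2 fold change of -0.28 (adjusted p = 0.0118, 0.0132 with pairs summed, 0.843 with an estimated correlation, 0.0747 without low-yield 2 and 5). Without low-yield 5 alone the median was -0.08 (adjusted p = 0.910) and without low-yield 2 alone -0.37 (adjusted p = 1.22e-06), as the list score was 1.43 in low-yield 5 and -1.09 in low-yield 2. Nor was the list called without high-yield 1, 4, 5 or 8 or low-yield 1 (adjusted p from 0.0510 to 0.0853), or with no low-count filter. No member passed over all genes or adjusted over the list alone (0 of 242). ZP1 (LOC117972689) stood at 574 ± 199 CPM in high-yield and 1279 ± 711 CPM in low-yield ovaries, and a second ZP1 row (LOC131699595), a ZP3 row (LOC131722046) and a uromodulin row (LOC117413660) had log2 fold changes of -0.86, -1.14 and -3.08.

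**Figure D4:**
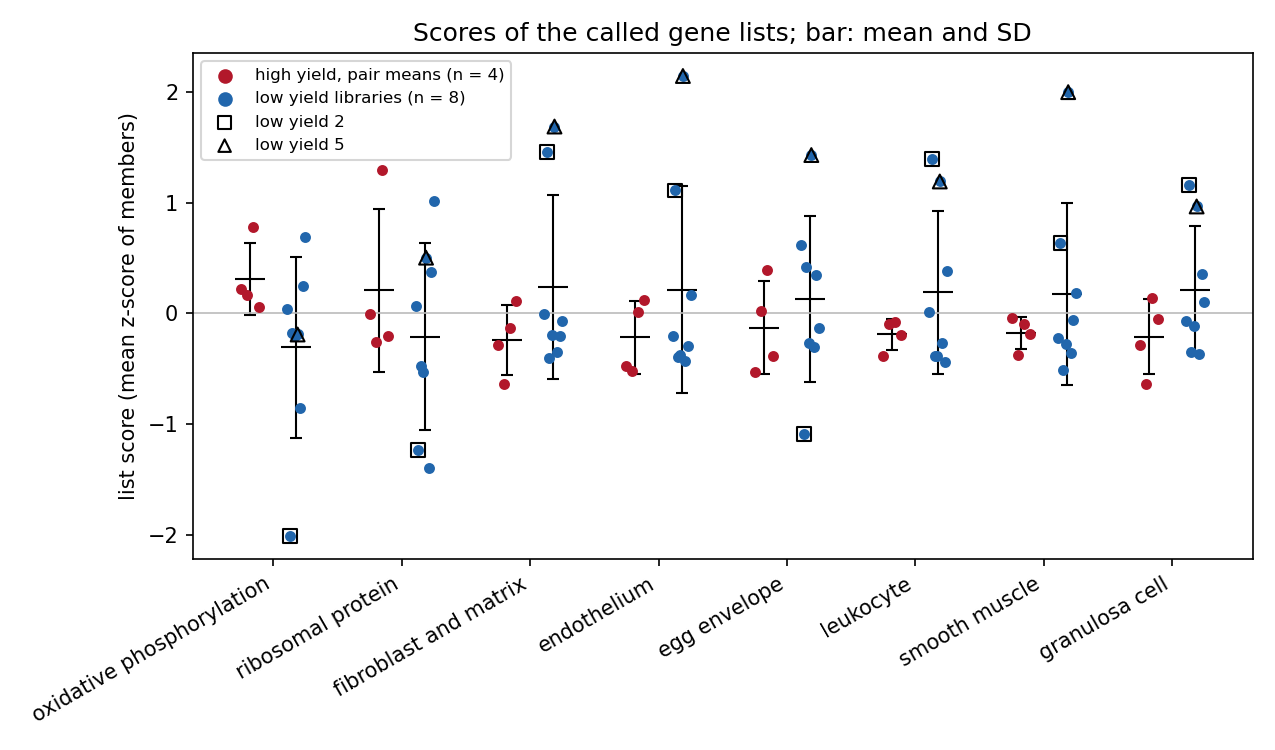
Scores of the 8 called gene lists, the mean z-score of their members in log2 CPM (red, 4 high-yield pair means; blue, 8 low-yield libraries; bars, mean and SD). Low-yield 2 (square) and 5 (triangle) hold the highest fibroblast and matrix, endothelium, leukocyte, smooth muscle and granulosa cell scores, and low-yield 2 the lowest oxidative phosphorylation score, -2.02.

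The remaining lists were not called over 16 libraries, nor with pairs summed. Camera adjusted p was 0.900 for steroidogenesis, 0.910 for hormone receptors, 0.900 for follicle growth factors, 0.699 for theca and testis-type genes, 0.266 for oocyte and germ cell genes, 0.204 for meiotic prophase, 0.487 for cell cycle and maturation and 0.980 for yolk uptake and processing. In lipid metabolism it was 0.984 for lipid storage and uptake, 0.559 for fatty acid synthesis and oxidation and 0.266 for cholesterol synthesis. Marker lists of other tissues had 0.139 for adipose cells, 0.900 for red blood cells, 0.840 for skeletal muscle and 0.204 for liver-type genes. The remaining values were 0.139 for the mitochondrial genome, 0.142 for stress and immediate early genes, 0.678 for the unfolded protein response, 0.116 for apoptosis and atresia, 0.293 for autophagy and lysosome, 0.116 for antioxidant genes, 0.984 for complement and acute phase, 0.204 for the interferon response and 0.0773 for PI3K, AKT, mTOR and insulin signalling. Among these, some were called under an alternative: antioxidant, meiotic prophase and stress genes with limma on log2(FPKM + 1), antioxidant genes also with a pseudocount of 0.1 or a mean FPKM of at least 5, apoptosis and atresia with no low-count filter, PI3K signalling with a mean FPKM of at least 5 or without high-yield 2 or 6, stress genes without low-yield 4 or 6, the mitochondrial genome without low-yield 5, without low-yield 2 and 5 or with the covariate, and cholesterol synthesis without low-yield 2 and 6. Median, mean and test differed in sign for the mitochondrial genome (median -1.04, tested direction higher), skeletal muscle, steroidogenesis, hormone receptors, yolk uptake, oocyte, and complement lists. In an exact two-sided permutation test of the list scores, 0 of 32 lists passed over 16 libraries (smallest adjusted p = 0.149) and 0 over pair means (smallest adjusted p = 0.646).

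Genes named in advance for their part in egg growth did not pass the gene test, over 16 libraries or with pairs summed. The vitellogenin receptor vldlr, through which oocytes take up yolk precursor, stood at 305 ± 41.0 CPM in high-yield and 320 ± 47.2 CPM in low-yield ovaries (log2 fold change -0.07, SE 0.13, adjusted p = 0.799). The oocyte growth factors GDF9 (LOC117431139) and BMP15 (LOC117430234) had log2 fold changes of 0.24 (SE 0.31) and 0.26 (SE 0.20). For the most abundant ZP3 row (LOC117963195), at 2896 ± 1019 against 3051 ± 1605 CPM, the value was -0.08 (SE 0.31), and for the germ cell helicase vasa (LOC117409552) -0.64 (SE 0.23, adjusted p = 0.153). Estrogen receptor genes gave 0.62 (esr1, SE 0.53) and -1.16 (LOC117419823, SE 0.74). Without low-yield 5 these were 1.25 and -0.73, and without low-yield 2 they were 0.67 and -0.61. Transcripts at low mean counts, from 22.8 to 99.8 per library, included the gonadotropin receptors, with FSHR (LOC117410409) at -1.43 (SE 1.17) and lhcgr at -2.04 (SE 0.98), and also aromatase (LOC117428169, 0.41, SE 0.76), FOXL2 (LOC117416901, -1.68, SE 0.89), StAR (LOC117397793, -0.79, SE 0.52) and LRP8 (LOC117417398, -0.87, SE 0.52). FOXL2 and LRP8 rested on low-yield 2, with values of -0.43 and -0.09 without it. The lhcgr transcript stood at 11.5 and 7.065 CPM in low-yield 2 and 5, against 0 to 3.27 CPM in the other low-yield libraries.

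Of the lipid genes named in advance, perilipin-1 (LOC117428569), a coat protein of fat droplets, came closest to the threshold over 16 libraries. It stood at 0.783 ± 0.229 CPM in high-yield and 7.49 ± 12.6 CPM in low-yield ovaries, with 38.4 CPM in low-yield 2. The log2 fold change was -3.26 (SE 0.70, edgeR adjusted p = 0.0649), and -3.20 with pairs summed (SE 1.02, edgeR adjusted p = 0.574). Its log2 fold change was -1.97 without low-yield 2, and it passed without low-yield 8 (adjusted p = 0.0341). Lipoprotein lipase (LOC117401443, -0.03, SE 0.36), CIDEC (LOC117962611, -0.04, SE 0.14) and adiponectin (LOC117422945, 0.88, SE 1.16) did not pass either. Adiponectin stood at 1.72 and 2.05 CPM in high-yield 2 and 6, against 0 to 0.449 CPM in the other high-yield libraries. In low-yield 2 it stood at 1.45 CPM, against 0 to 0.451 CPM in the other low-yield libraries. Vitellogenin (LOC117416999), made mainly in the liver, stood at 1.03 ± 0.850 against 1.14 ± 0.711 CPM. The log2 fold change was -0.55 (SE 0.71) for the leukocyte gene PTPRC (LOC117401721; 0.034 without low-yield 2 and -0.24 without low-yield 5), -0.42 (SE 0.43) for a hemoglobin subunit (LOC117418307), -1.78 (SE 0.71) for the most abundant collagen I alpha-1 row (LOC117434956; -0.70 without low-yield 5, which had 625 CPM), -0.32 (SE 0.41) for IGF1 (LOC117962376) and 0.49 (SE 0.72) for IGF2 (LOC117435150). CYP17A1 (LOC117409034), with a mean of 23.4 counts, was below the count filter, and cyp11a1, lrp13 and figla were not matched to a row and are not analysed here.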

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

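Chosen only after the result was seen were the splits of the pair-summed counts for genes, the dispersion test of the pairs, the tests without low-yield 2 and 5 or 2 and 6, the hemoglobin tests and the group tests of the fibroblast and oxidative phosphorylation scores.

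The 4 near-identical high-yield pairs were weighed first. The counts differed within each pair by a median dispersion of at least 4.19 times Poisson, which argues against the same reads listed under 2 names, although counts computed from coverage need not follow Poisson sampling. At most 0.462% of expressed genes were on in 1 library and absent in its partner, below the lowest value of any other pair of libraries (0.969%). This measure is among those by which the pairs were found and any cause of near identity would give it, so it does not test whether 2 libraries of the same fish are the cause, which stays open and may be so although the labels give 8 fish. If so, the high-yield group holds 4 independent samples, for which edgeR called 0 genes on the summed counts (2557 at an unadjusted p under 0.05) and DESeq2 called 86, all 16 genes among them, with 69 false calls in simulated data of this size.

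The split tests bear on this count. Of 100 drawn splits of 16 libraries, 2 gave at least 16 genes, the real one included, with 233 as the highest other, but random splits part the near-identical pairs and the real split does not. Of 100 drawn from the 323 splits that keep the pairs whole, 19 gave at least 16 genes, so chance is not excluded. The highest other, 6694 genes, put high-yield 1, 2, 5 and 6 with low-yield 2, 3, 5 and 6, which points to a structure of the samples that the yield groups do not follow. With pairs summed, edgeR called 0 genes (2557 at an unadjusted p under 0.05, and 86 by DESeq2), and the 100 of 100 splits with at least as many follow from the count of 0 and say nothing about chance, with 284 as the highest other. For lists chance is not excluded either: 38 of 100 splits called at least 8 (highest other 16), 58 of 100 called at least 7 with pairs summed (highest other 19), and 40 of 100 that keep pairs whole called at least 8 (highest other 16).

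The lower fibroblast and matrix, endothelium, leukocyte, smooth muscle and granulosa cell lists in high yield were weighed next. Without low-yield 2 and 5, 0 of the 5 lists stayed called, so these 2 libraries may carry the difference. Blood carried in low-yield library 2 is argued against by its summed hemoglobin, 0.471 times the median of the other 6 low-yield libraries. Its collagen I alpha-1 stood at 9.27 times theirs. Its red blood cell list score went the other way, at 0.416 against -0.293 to 0.22 in those 6, so blood in this library is not excluded. For blood in low-yield library 5 the ratio was 1.70, above the highest of the 6 but under 2, which leaves it open, beside a collagen ratio of 25.2. An effect of the yield group, which cannot be told apart from one of the population, stays open as well (exact permutation p = 0.299 for the fibroblast and matrix score, 4 pair means against 8). So do a piece of ovary with more stroma, another follicle stage, or RNA or library quality, none of them tested. These 2 libraries also had the highest rRNA shares (0.114% and 0.224%, against 0.013% to 0.057% in the others) and the most genes with counts (36856 and 34696).

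The higher oxidative phosphorylation and ribosomal protein lists were the last pattern weighed. For transcript length, 0% of 10000 random lists matched on expression and on the derived length reached the oxidative phosphorylation median of 0.37. The derived length had a median of 3098.6 nt in this list and 3037.7 nt in the ribosomal protein list, against 2921.1 nt over all tested genes. It comes only from the ratio of counts to FPKM and may not track the true length, so the draws do not decide on a length effect. Low-yield libraries 2 and 6 had the lowest scores in both lists, and without them 1 of the 2 lists, oxidative phosphorylation, stayed called (adjusted p = 0.00271). The yield group may be the cause, though it cannot be told apart from the population. The exact permutation p of the oxidative phosphorylation score was 0.1475 over 4 pair means and 8 libraries, and the 142 members share a program, so they are not independent. None of these explanations is excluded, and no call held with an estimated correlation.

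A single sample stood far from the others of its group in 22 of 172 groups tested by Dixon's ratio. For independent, normally distributed values the critical values would give about 1 in 20, or 8.6. The CPM values were not log-transformed, and many of the genes were picked from these same data. The 22 groups therefore do not show an excess over chance. Low-yield 5 was the sample in 9 of the 22 groups. Its CPM was far above the others for the ZP3 row LOC131722046 (ratio 0.547), cadherin-5 (0.794), col6a3 (0.622), RPL13A (0.578), myosin-11 (0.719), smooth muscle myosin light chain kinase (0.875), esr1 (0.691) and collagen I alpha-1 LOC117434956 (0.643), as was its smooth muscle score (0.541). Low-yield 2 was the sample in 5, with high filamin-B (0.605), FOXL2 (0.788), LRP8 (0.908), adiponectin (0.689) and perilipin-1 (0.847). Low-yield 8 was high in gamma-sarcoglycan (0.531), at 24.4 CPM against 4.62 to 13.9 CPM in the others.

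In high yield a pair mean stood apart in 7 groups. The pair 4 and 8 was low in FKBP11 (ratio 0.951, 23.0 CPM against 37.2 to 37.9). The pair 1 and 5 was low in SGT1 (0.855) and high in ST6GAL2 (0.853). The pair 3 and 7 was high in NDUFB5 (0.930), RPL10A (0.936, 731 CPM against 258 to 288), the ZP3 row LOC117963195 (0.852) and the ribosomal protein score (0.838).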

How the results depend on the processing

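Pair-summed counts, high-yield libraries 1 to 4, the pair as a random effect, omission of low-yield 2 and 5 or 2 and 6, library size only and symbols only were chosen after the data were seen.

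The count of genes called by edgeR, 16, was 4 with no low-count filter (median log2 fold change of all genes -0.11, against -0.03), 44 with a mean FPKM of at least 5, 26 with median-of-ratios scaling, 9 with the non-follicle marker component as covariate, 3 with library size only and 3 without low-yield 2 and 5. DESeq2 called 1624 and the exact rank-sum permutation test 98. Of the 16 genes, 4 were among those called with no low-count filter, 8 with a mean FPKM of at least 5, 16 with median-of-ratios scaling, 5 with the covariate, 2 with library size only, 1 without low-yield 2 and 5, 16 by DESeq2 and 8 by the rank-sum test. Limma on log2(FPKM + 1), the test chosen for a table without raw counts, called 3 genes, 1 of them among the 16. It called 4 with a pseudocount of 0.1, 4 with 5, 3 with a mean FPKM of at least 5, 80 with median-of-ratios scaling, 6 with equal FPKM sums, 3 with robust eBayes, 10728 with array weights, and 0 with no filter (4997 at an unadjusted p under 0.05). With high-yield pairs summed edgeR called 0 (2557 unadjusted) and DESeq2 86. Counts were also 0 with high-yield libraries 1 to 4 (edgeR, 2567 unadjusted), with voom and the pair as random effect (2460), and with pairs summed without low-yield 2 and 5 (edgeR, 3630). Leaving out 1 library gave 0 to 536 genes. Robust edgeR dispersion (23 genes) and limma on quantile-normalized values (16) stayed within 1.5 times the count. The cause of these moves was not tested. Summed or omitted libraries leave fewer samples, but omission also raised the count, to 536 without low-yield 8. Summing also ends the counting of near-identical libraries as independent.

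The replicate block called 0 genes (edgeR, 4627 unadjusted). Deviations from the group mean correlated between libraries of 1 number by -0.179 to 0.404, and 3 of 8 high-yield libraries correlated best with their own number. With near-identical high-yield pairs this check cannot decide whether the numbers pair the groups. The labels give no such pairing.

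The count of called lists, 8, was 0 with an estimated correlation, 0 with fry, 0 with pairs summed and an estimated correlation, 3 with the covariate, 3 without low-yield 2 and 5, 3 with pairs summed without these, and 1 with symbols only, where 12 lists could be tested. With a mean FPKM of at least 5 the endothelium and granulosa cell lists had too few members to test. With the covariate and without low-yield 2 and 5, 2 of the 3 were among the 8, and the other was the mitochondrial genome list. Leaving out 1 library gave 3 to 9. The median log2 fold change reversed in endothelium to 0.25 with the covariate, 0.12 without low-yield 2 and 5 and 0.15 with pairs summed without them, in fibroblast and matrix to 0.13, 0.050 and 0.014, in smooth muscle to 0.13, 0.15 and 0.17, and in leukocyte to 0.19 with the covariate and 0.089 without low-yield 2 and 5. The covariate is built from these marker lists, so it removes their shift by construction. For the others, the 2 omitted libraries are those with the highest scores of these lists.

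By the tested direction, called lists kept direction and threshold in 177 comparisons, lost the threshold in 62 and reversed in 10; the leukocyte list without low-yield 2 and 5 is among the 62, since its tested direction stayed lower while its median turned positive. Named genes that were called kept it in 171 and lost it in 387 with 0 reversed, and genes not called stayed so in 2258 and passed in 110. Low counts limit FSHR, CYP17A1, adiponectin, aromatase and StAR, whose means ran from 22.8 to 26.1 counts.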

Other observations

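The pathway tests and the values of the mitochondrial genome list without low-yield 2 and 5 were chosen after the data were seen.

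Of 277 pathways given in the table, camera with its preset correlation called 39 over 16 libraries, 10 higher and 29 lower in high yield, and 40 with pairs summed, 39 of them in both. With an estimated correlation 0 were called. Oxidative phosphorylation (235 genes, median log2 fold change 0.29, adjusted p = 1.44e-08) and ribosome (264 genes, 0.24, 7.34e-06) were higher, and without low-yield 2 and 5 their adjusted p was 0.000614 and 0.0139. Protein digestion and absorption, a set rich in collagens (399 genes, -1.03, 1.44e-08), and ECM-receptor interaction (416 genes, -0.94, 3.85e-06) were lower, and without low-yield 2 and 5 their adjusted p was 0.993 and 0.979. Of the 29 lower pathways 9 were still called lower without low-yield 2 and 5. Among them were viral myocarditis (107 genes, adjusted p = 0.00957), leukocyte transendothelial migration (115 genes, 0.0139) and Hippo signaling (152 genes, 0.0323). Dilated cardiomyopathy (106 genes), viral myocarditis and hypertrophic cardiomyopathy (108 genes) each had a median log2 fold change of -0.29. Such pathways may share many genes, which was not tested, so the 9 need not be separate results. Of the 10 higher pathways 2 were still called, the higher pair given above.

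The 13 genes of the mitochondrial genome list had a median log2 fold change of -1.04 over 16 libraries and 1.70 without low-yield 2 and 5 (adjusted p = 1.23e-06, 0.844 with an estimated correlation). Mitochondrial transcripts took 0.929% of the counts in low-yield 5, 0.234% in low-yield 2 and 0.014% in low-yield 6. In poly(A)-selected libraries these shares also depend on the capture of mitochondrial RNA.

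The apoptosis and atresia score had pair means of 0.445 and 0.430 in high-yield 1 with 5 and 2 with 6, and -0.239 and -0.123 in 3 with 7 and 4 with 8, the same division as on the first principal component. Low-yield 5, at the same end of that component as high-yield 1, scored 0.086. The division is not particular to this list. The mitochondrial genome, unfolded protein response and red blood cell scores divided the pairs in the same direction and endothelium in the opposite one, while oxidative phosphorylation did not divide them so. A link of any list with the component was not tested.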
